A study of Homo sapiens with 36 samples.

How the data were processed

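RNA of human AML cell lines was sequenced in 36 libraries, per the labels: 12 of wild-type OCI-AML3, 12 of wild-type TF-1a, and 12 of TF-1a with HSF1 intact or knocked out. Per the labels' protocols, RNA was extracted with the RNAeasy Plus Mini kit, libraries were made by SMARTseq2 and sequenced in 2 lanes. This protocol does not keep the strand, so a gene cannot be told apart from an antisense partner that overlaps it. Per the submitters' processing notes, the authors used FastQC, Trim Galore, HISAT2, DESeq2 1.40.2 and the genome build GRCh38. The gene counter and the annotation were not given in the sources used here. Treatment time (24 h) came from the series description.

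The authors deposited 3 tables of normalized read counts, one for each set of 12 libraries. The deposited signal values were the gene read counts divided by a size factor for each library, as made by the median-of-ratios method of DESeq2. Whole reads were recovered by finding the step of each library: 100% of the values were whole multiples of it, with a tolerance of 0.1. These recovered reads served for depth and for the count-based tests only. The size factors of the HSF1 table were reproduced from its 12 libraries alone (17800 genes above 0 in each), and those of the OCI-AML3 and TF-1a tables from their 24 libraries as one set (13798 genes). Taken alone, they deviated by up to 1.56% and 2.73%. The design written earlier had taken the tables as separate scales, so the tests within each line were kept as planned, and tests between the lines were added later. The HSF1 table held no mitochondrial genes. It listed 39201 features, and each of the others listed 39813. Gene positions came from GENCODE 29 on GRCh38.

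Libraries had 8.54 to 31.5 M recovered reads, with the lowest depth in the combination groups. Counting error of HSF1 was small, with at least 2632 reads in each library of its table. Reads are not independent molecules, since the protocol carries no molecular identifiers. None of the 36 pairs of replicates were identical. Groups followed the labels. Levels of sex-linked marker genes were not reported. Results for some genes withheld for evaluation are not reported here.

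The main test was the trended limma test (limma 3.58.1, R 4.3.3) on log2 of the deposited value plus 1, in genes with a mean of at least 10 over the 12 libraries of a table: 15137 in OCI-AML3, 15296 in TF-1a and 15861 in the HSF1 series. One fit per table held its 4 groups, and p-values were adjusted over genes by the Benjamini-Hochberg method with a threshold of 0.05. In all, 15 contrasts were tested, each table with 4 comparisons of groups and 1 interaction. The 28 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 (two-sided, adjusted over the lists of a contrast) and again with the correlation estimated from the data. Lists included proteasome subunits, ubiquitin and p97, heat shock, ER unfolded protein response, ATF4, NRF2 and NF-kB targets, autophagy, lysosome, cholesterol, cell cycle, MYC and ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, immediate early genes as a sign of handling, mitochondrial transcripts as a sign of RNA quality, and markers of other cell types.

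Genes named in the text followed a rule fixed with the design: HSF1, the 5 genes with the largest change in each direction among those called, with a mean of at least 50 in the higher group and no overlap between the groups (3 in each direction for interactions), up to 4 members of each list, and a fixed panel of stress, degradation and cell state genes. Sex-linked genes and names of clones were left out. For OCI-AML3 under a single drug, where the main test called 0 genes, the rule was applied to the planned fit of only the 2 groups. Mitochondrial genes and MALAT1 were chosen after their values were seen. HSPA1A and HSPA1B share most of their sequence, so their values are uncertain.

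Whether replicate numbers pair the samples was checked by the correlation of deviations from the group means, with a threshold of 0.1 in every pair. The numbers paired the samples by this check, from the data and not from the labels, for carfilzomib and control in OCI-AML3 (0.488, 0.295 and 0.644), Lys05 and control in OCI-AML3 (0.165, 0.134 and 0.339) and carfilzomib and control in TF-1a (0.298, 0.151 and 0.298). In the other 9 comparisons they did not.

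Alternatives fixed in advance were a pseudocount of 8, no filter on low values, rescaled libraries, the replicate number as a block, fits of only the groups compared, edgeR 4.0.16, DESeq2 1.42.0 and each library left out in turn. Alternatives added after seeing the data were the 2-group fits with the block, and fits without the libraries labelled carfilzomib plus Lys05 replicate 3 of each line or OCI-AML3 Lys05 replicate 1. Also added then were the tests of TF-1a against OCI-AML3 responses, in one limma fit of both tables over 14828 (carfilzomib) and 14844 genes (Lys05). Line-specific genes had at least 50 normalized reads in each control library of one line and at most 1 in each of the other. Their level was compared with their mean in their own line under the same treatment (at least 20), without the libraries labelled replicate 3 for the combination. The outlier test was not run, since groups held 3 libraries. Every column of per-sample values was used.

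The main test was checked on simulated data made from the control libraries. Changes of 1.5, 2 and 4 times were recovered at 45.3%, 69.1% and 98.3% in OCI-AML3 (14009 genes, 6 false of 130 calls). Shares were 66.1%, 93.8% and 98.4% in TF-1a (14372 genes, 14 false of 174) and 68.9%, 85.9% and 96.9% in the HSF1 series (15462 genes, 16 false of 176). The planted list was found in each, with 0 false lists. Python work used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.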

Results

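The transcriptomes of 36 libraries of human acute myeloid leukaemia (AML) cell lines were measured by RNA sequencing, in 12 groups of 3 libraries. Wild-type OCI-AML3 (a myelomonocytic AML line) and wild-type TF-1a (an erythroleukaemia-derived line) each had 4 groups: control, carfilzomib, Lys05, and carfilzomib plus Lys05. Carfilzomib is an irreversible inhibitor of the proteasome. Lys05 is a dimeric chloroquine derivative that blocks lysosomal degradation and thereby autophagy. In a further series, TF-1a cells with intact HSF1 (HSF1+/+) or with HSF1 knocked out by guide RNA (HSF1-/-) received no drug or carfilzomib. HSF1 is the transcription factor that drives the heat shock response. Treatment lasted 24 h per the series description, and the doses were not given.

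The reads recovered from the deposited normalized counts summed to 22.7 to 30.4 M reads (M, mega) per library in the HSF1 series. The OCI-AML3 libraries had 22.4 to 29.9 M (control), 20.1 to 25.7 M (carfilzomib) and 23.8 to 26.03 M (Lys05), and the libraries labelled OCI-AML3 carfilzomib plus Lys05 had 20.2, 8.54 and 12.8 M. The TF-1a libraries had 25.2 to 29.8 M (control), 21.4 to 27.7 M (carfilzomib) and 28.3 to 31.5 M (Lys05), and those labelled TF-1a carfilzomib plus Lys05 had 12.6, 14.6 and 11.1 M. Errors are the SD for means and the standard error of the limma fit for log2 fold changes (n = 3 libraries per group), and gene values with no other unit are log2 fold changes. For each gene list, parentheses give the members that rose, fell or did not pass over all genes and the median log2 fold change. The adjusted p of a list is that of the camera test in limma, with a preset correlation and again with an estimated one. Nothing in the labels states that replicates came from separate cultures, so p-values measure the spread between these libraries only.

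A check of cell line identity came first, since 2 libraries stood apart from their groups. In controls, 200 genes were specific to OCI-AML3, among them the granule protease CTSG, and 306 were specific to TF-1a. In the library labelled OCI-AML3 carfilzomib plus Lys05 replicate 3, the OCI-AML3-specific transcripts had a median of 0.141% of their level in OCI-AML3 under the same treatment, and the TF-1a-specific transcripts had 104.2% of their level in TF-1a. The library labelled TF-1a carfilzomib plus Lys05 replicate 3 had a median of 0% for the TF-1a-specific transcripts and 125.4% for the OCI-AML3-specific ones. Across 15549 genes, the first of these libraries correlated at 0.971 with each library labelled TF-1a combination replicate 1 and 2, and at 0.623 and 0.660 with those labelled OCI-AML3 (Pearson, across genes, which are not independent replicates). The library labelled OCI-AML3 Lys05 replicate 1 carried TF-1a-specific transcripts at a median of 3.30% of the TF-1a level, against 0% in its replicates 2 and 3. No library was moved to another group. Counts, named genes and list medians of the combination groups are given with and without the library labelled replicate 3, and those of OCI-AML3 Lys05 against control with and without replicate 1. These libraries enter the error term of every 4-group fit of a line. Counts and list tallies of single drugs are thus also given from fits of only the 2 groups, with the same log2 fold changes but other errors.

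**Figure D1:**
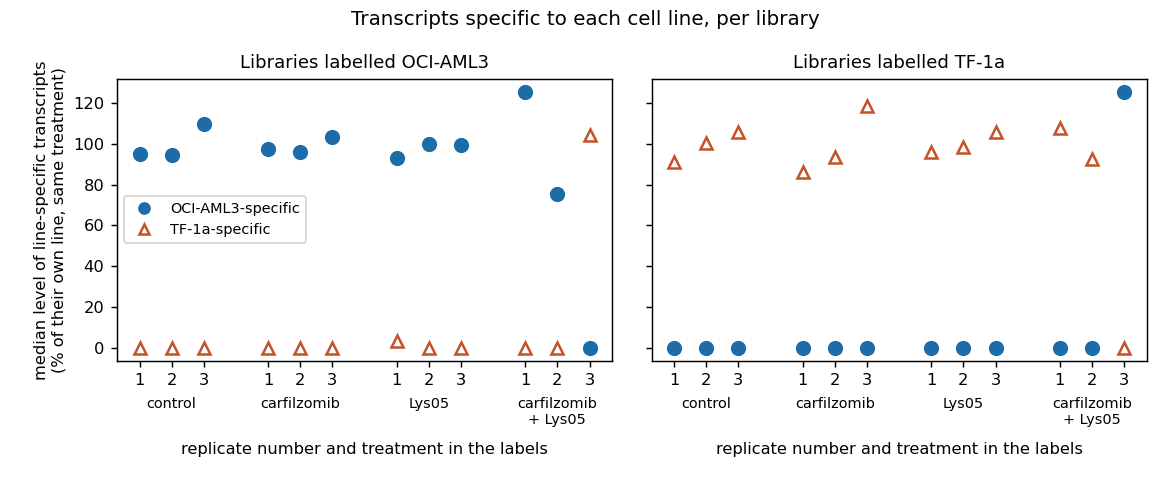
Median level of the transcripts specific to OCI-AML3 (filled circles) and to TF-1a (open triangles) in each library, as a percentage of their level in their own line under the same treatment; the x axis gives the replicate number and treatment in the labels. The libraries labelled carfilzomib plus Lys05 replicate 3 lay at 104.2% and 125.4% for the other line's transcripts.

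The HSF1-/- against HSF1+/+ comparison in untreated TF-1a cells asked how the knockout differed in transcription at baseline. The labels do not say whether it is a single clone or a pool, so differences between the genotypes may include differences between clones. HSF1 itself (ENSG00000185122, GRCh38 chromosome 8, 144291591 to 144314722) had 9367, 9665 and 9302 normalized reads in the HSF1+/+ control libraries and 11222, 12001 and 11128 in HSF1+/+ with carfilzomib. It had 2654, 3044 and 3073 in the HSF1-/- control libraries, 31.0% of the HSF1+/+ control mean, and 5250, 7402 and 6992 in HSF1-/- with carfilzomib. HSF1 fell on the log2 scale by the fit (-1.69 ± 0.12, limma adjusted p = 2.62e-06), so the transcript was lower, not absent. Genes of the heat shock response shifted downward together (0 of 28 were higher, 13 lower, 15 did not pass, median -0.66). The heat shock list had adjusted p = 1.48e-11, and adjusted p = 0.454 with an estimated correlation, and 0 were higher and 21 lower adjusted over the list alone. The chaperone gene HSPH1 (ENSG00000120694, chromosome 13, 31134974 to 31162388) fell from 7552 ± 417 to 1329 ± 249.8 normalized reads (-2.52 ± 0.23, adjusted p = 2.09e-05). The Hsp90 gene HSP90AA1 (-1.22 ± 0.17), the co-chaperone gene DNAJA1 (-1.21 ± 0.19) and the Hsc70 gene HSPA8 (-0.94 ± 0.25, adjusted p = 0.0313) fell as well. DNAJB1 (-0.91 ± 0.33, adjusted p = 0.1003), HSPB1 (-0.69 ± 0.26, adjusted p = 0.116) and BAG3 (-0.46 ± 0.24, adjusted p = 0.253) did not pass.

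Other gene groups also differed between the untreated genotypes. The ribosomal protein genes shifted upward (19 of 50 were higher, 0 lower, 31 did not pass, median 0.28). The ribosomal protein list had adjusted p = 4.36e-12, and adjusted p = 0.712 with an estimated correlation, and 31 were higher and 1 lower adjusted over the list alone. ATF4 target genes also shifted upward (4 of 30 were higher, 1 lower, 25 did not pass, median 0.40). The ATF4 list had adjusted p = 0.000406, and adjusted p = 0.799 with an estimated correlation, and 8 were higher and 1 lower adjusted over the list alone. TFEB, a regulator of lysosomal genes, fell (-1.10 ± 0.18, adjusted p = 0.00155), while ALAS2, the erythroid enzyme of haem synthesis, rose (1.33 ± 0.11, adjusted p = 7.95e-06). The largest differences included genes near 0 in one of the genotypes. The mechanosensitive channel gene PIEZO2 had 242 ± 27.9 normalized reads in HSF1+/+ and was listed at 0 in HSF1-/-, and the T-cell receptor subunit gene CD3D (-5.13) and the cadherin gene CDH5 (-7.59) were also lower. NMNAT3 (3.82 ± 0.37), an enzyme of NAD synthesis, and the steroid hydroxylase gene CYP17A1 (3.20 ± 0.42) were higher. In all, 1853 of 15861 genes passed, of which 677 rose and 1176 fell (limma, adjusted p below 0.05). The groups did not overlap for 1851 of these and for 45.1% of all genes, against 10% expected by chance with 3 and 3 libraries. A fit of only these 2 groups called 4874 genes. The call count was 3222 and 3128 without HSF1-/- carfilzomib replicate 1 or 3, 958 and 1115 without HSF1-/- control replicate 2 or 3, and 1106, 898 and 1015 without HSF1+/+ control replicate 1, 2 or 3.

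**Figure D2:**
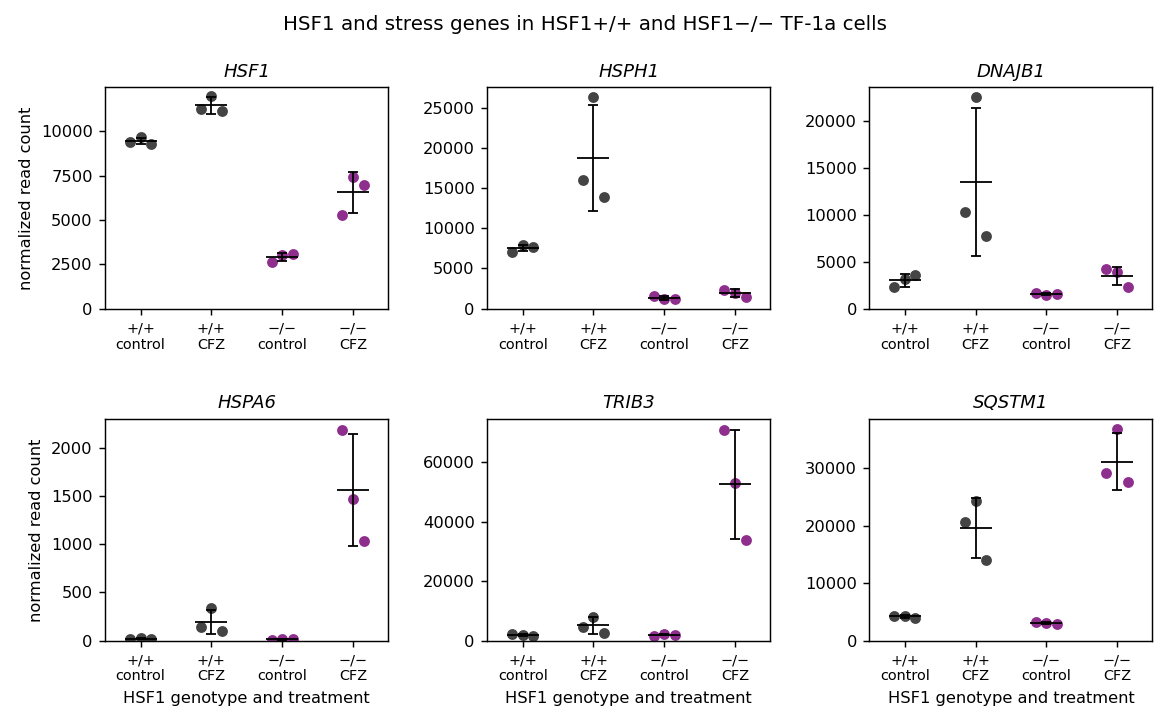
Normalized read counts of 6 genes in HSF1+/+ and HSF1-/- TF-1a cells without drug (control) or with carfilzomib (CFZ); points are the 3 libraries of a group, and bars give the mean ± SD. HSF1 had a mean of 2924 in HSF1-/- control and 9445 in HSF1+/+ control.

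Carfilzomib against control in HSF1+/+ cells asked how TF-1a cells with intact HSF1 respond to proteasome inhibition. Nearly every gene for a proteasome subunit rose (32 of 33 rose, 0 fell, 1 did not pass, median 0.94), with PSMC4 at 1.32 ± 0.13, PSMD14 at 1.35 ± 0.16 and ADRM1 at 1.35 ± 0.14. The proteasome list had adjusted p = 7.90e-18, and adjusted p = 0.226 with an estimated correlation, and 32 rose and 0 fell adjusted over the list alone. The p97 cofactor gene NPLOC4 (1.22 ± 0.17) rose with the ubiquitin pathway (16 of 21 rose, 1 fell, 4 did not pass, median 0.77). The ubiquitin list had adjusted p = 1.32e-07, and adjusted p = 0.171 with an estimated correlation, and 16 rose and 1 fell adjusted over the list alone. The heat shock response rose (20 of 28 rose, 1 fell, 7 did not pass, median 0.73), with DNAJB1 at 2.04 ± 0.33, the co-chaperone gene BAG3 at 1.57 ± 0.24 and HSPH1 at 1.26 ± 0.23. For the heat shock list, 21 rose and 1 fell adjusted over the list alone, with adjusted p = 2.62e-08, and adjusted p = 0.236 with an estimated correlation. Genes of the endoplasmic reticulum (ER) unfolded protein response rose as well (21 of 24 rose, 0 fell, 3 did not pass, median 0.75), including the ER chaperone gene HSPA5 (1.91 ± 0.20). The ER unfolded protein response list had adjusted p = 5.06e-09, and adjusted p = 0.182 with an estimated correlation, and 21 rose and 0 fell adjusted over the list alone.

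The autophagy list also moved upward in HSF1+/+ cells (23 of 37 rose, 0 fell, 14 did not pass, median 0.49), led by the cargo receptor SQSTM1 (2.19 ± 0.17, ENSG00000161011, chromosome 5, 179806398 to 179838078) and GABARAPL1 (2.11 ± 0.14, ENSG00000139112, chromosome 12, 10212458 to 10223130). The autophagy list had adjusted p = 8.75e-08, and adjusted p = 0.135 with an estimated correlation, and 26 rose and 0 fell adjusted over the list alone. Targets of NRF2, the regulator of antioxidant genes, rose (14 of 20 rose, 0 fell, 6 did not pass, median 1.00), among them haem oxygenase HMOX1 (3.10 ± 0.47). The NRF2 list had adjusted p = 1.59e-07, and adjusted p = 0.146 with an estimated correlation, and 14 rose and 0 fell adjusted over the list alone. Lysosomal genes moved in the same direction (24 of 45 rose, 2 fell, 19 did not pass, median 0.38), with CTSD, the gene of cathepsin D, at 1.61 ± 0.19. The lysosome list had adjusted p = 1.14e-06, and adjusted p = 0.135 with an estimated correlation, and 25 rose and 3 fell adjusted over the list alone. Cholesterol synthesis genes shifted downward (1 of 25 rose, 12 fell, 12 did not pass, median -0.54). The cholesterol list had adjusted p = 0.000139, and adjusted p = 0.276 with an estimated correlation, and 1 rose and 13 fell adjusted over the list alone. Erythroid markers fell (0 of 20 rose, 10 fell, 10 did not pass, median -0.75), among them the erythroid transcription factor gene KLF1 (-1.41 ± 0.47). The erythroid list had adjusted p = 0.000138, and adjusted p = 0.276 with an estimated correlation, and 0 rose and 10 fell adjusted over the list alone. In all, 5868 of 15861 genes passed, 3068 rising and 2800 falling. The count was 3721 without HSF1+/+ carfilzomib replicate 2.

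In HSF1-/- cells, the same comparison asked how the response ran in the knockout, where HSF1 transcripts were lower but present. The proteasome genes rose in HSF1-/- cells as well (29 of 33 rose, 0 fell, 4 did not pass, median 0.92), with PSMD14 at 1.74 ± 0.16. For the proteasome list, 30 rose and 0 fell adjusted over the list alone, with adjusted p = 2.06e-08, and adjusted p = 0.330 with an estimated correlation. The heat shock list as a whole did not pass (12 of 28 rose, 7 fell, 9 did not pass, median 0.30). That heat shock list had adjusted p = 0.470, and adjusted p = 0.814 with an estimated correlation, and 12 rose and 7 fell adjusted over the list alone. HSPA6 (6.79 ± 0.38), an inducible Hsp70 gene, and DNAJB1 (1.11 ± 0.33) rose, the small heat shock protein gene HSPB1 fell (-1.03 ± 0.26), and HSPH1 stood at 0.51 ± 0.23 (adjusted p = 0.0689). The ATF4 targets of the integrated stress response rose (29 of 30 rose, 1 fell, 0 did not pass, median 2.00), with the growth factor gene GDF15 at 5.86 ± 0.33, the pseudokinase gene TRIB3 at 4.67 ± 0.35 and the proapoptotic factor gene DDIT3 (CHOP) at 2.27 ± 0.27. For the ATF4 list, 29 rose and 1 fell adjusted over the list alone, with adjusted p = 7.20e-09, and adjusted p = 0.321 with an estimated correlation. The cell cycle inhibitor CDKN1A rose by 6.82 ± 0.48 and the BH3-only gene PMAIP1 by 3.19 ± 0.31. Cell cycle genes fell (1 of 31 rose, 29 fell, 1 did not pass, median -1.37), among them PCNA (-2.67 ± 0.17), the sliding clamp of DNA replication. The cell cycle list had adjusted p = 2.13e-08, and adjusted p = 0.321 with an estimated correlation, and 1 rose and 30 fell adjusted over the list alone.

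Immediate early genes, a list that also responds to handling, rose in HSF1-/- cells (14 of 14 rose, 0 fell, 0 did not pass, median 4.15), with FOS at 6.17 ± 0.31. The immediate early list had adjusted p = 1.45e-07, and adjusted p = 0.278 with an estimated correlation, and 14 rose and 0 fell adjusted over the list alone. NF-kB targets rose (15 of 16 rose, 1 fell, 0 did not pass, median 2.35), with the chemokine gene CXCL8 at 8.78 ± 0.70. The NF-kB list had adjusted p = 2.65e-05, and adjusted p = 0.0558 with an estimated correlation, and 15 rose and 1 fell adjusted over the list alone. Nuclear genes of oxidative phosphorylation fell (1 of 42 rose, 39 fell, 2 did not pass, median -0.82). The oxidative phosphorylation list had adjusted p = 7.20e-09, and adjusted p = 0.339 with an estimated correlation, and 1 rose and 40 fell adjusted over the list alone. Cholesterol genes fell (2 of 25 rose, 20 fell, 3 did not pass, median -1.39). For the cholesterol list, 2 rose and 20 fell adjusted over the list alone, with adjusted p = 1.54e-05, and adjusted p = 0.278 with an estimated correlation. Erythroid markers were lower too (1 of 20 rose, 17 fell, 2 did not pass, median -1.87). For the erythroid list, 1 rose and 17 fell adjusted over the list alone, with adjusted p = 7.99e-06, and adjusted p = 0.278 with an estimated correlation. HSF1 itself rose by 1.15 ± 0.12 (adjusted p = 4.56e-06). The lists of epithelial and fibroblast markers, kept as a sign of other cell types, had 6 of 8 rising (adjusted p = 0.0306, adjusted p = 0.321 with an estimated correlation). In all, 11057 genes passed, of which 5465 rose and 5592 fell.

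The interaction of genotype and carfilzomib tested where the responses of HSF1-/- and HSF1+/+ cells differed. It passed for 6345 genes, with a more positive response in HSF1-/- for 3256 and a more negative one for 3089. The heat shock response list was lower in HSF1-/- (2 of 28 were positive, 14 negative, 12 did not pass, median -0.64), with the mitochondrial chaperonin gene HSPE1 at -1.95 ± 0.29, the crystallin gene CRYAB at -2.96 ± 0.63 and HSPB1 at -1.51 ± 0.37. The heat shock list had adjusted p = 0.000570, and adjusted p = 0.514 with an estimated correlation, and 2 were positive and 14 negative adjusted over the list alone. HSPA6 ran the other way (3.71 ± 0.53), and HSPH1 had -0.75 ± 0.33 (adjusted p = 0.0869). The proteasome list did not pass (1 of 33 were positive, 6 negative, 26 did not pass, median -0.03), with the catalytic subunit gene PSMB5 at -0.03 ± 0.13 (adjusted p = 0.885). That proteasome list had adjusted p = 0.780, and adjusted p = 0.912 with an estimated correlation, and 0 were positive and 0 negative adjusted over the list alone. The responses of ATF4 targets were larger in HSF1-/- (22 of 30 were positive, 1 negative, 7 did not pass, median 1.23), with GDF15 at 5.07 ± 0.47 and TRIB3 at 3.45 ± 0.49. That ATF4 list had adjusted p = 6.37e-07, and adjusted p = 0.514 with an estimated correlation, and 22 were positive and 1 negative adjusted over the list alone. Those of immediate early genes were larger (13 of 14 were positive, 0 negative, 1 did not pass, median 2.80). For the immediate early list, 13 were positive and 0 negative adjusted over the list alone, with adjusted p = 1.19e-08, and adjusted p = 0.322 with an estimated correlation. NF-kB targets also had larger responses (12 of 16 were positive, 0 negative, 4 did not pass, median 1.59). For the NF-kB list, 12 were positive and 0 negative adjusted over the list alone, with adjusted p = 2.12e-05, and adjusted p = 0.0435 with an estimated correlation, where it still passed. Cholesterol synthesis genes had more negative responses in HSF1-/- (2 of 25 were positive, 16 negative, 7 did not pass, median -0.77). That cholesterol list had adjusted p = 0.000532, and adjusted p = 0.471 with an estimated correlation, and 2 were positive and 16 negative adjusted over the list alone. The responses of cell cycle genes were more negative as well (0 of 31 were positive, 18 negative, 13 did not pass, median -0.98). For the cell cycle list, 0 were positive and 19 negative adjusted over the list alone, with adjusted p = 2.12e-05, and adjusted p = 0.514 with an estimated correlation. Markers of other cell types also differed, with the lymphoid genes IL7R at 7.67 ± 0.90 (adjusted p = 0.000131) and TRAC at 5.54 ± 0.84 (adjusted p = 0.000582). Of the epithelial and fibroblast markers, 5 of 8 were positive and 0 negative (adjusted p = 0.0173, adjusted p = 0.471 with an estimated correlation). The lymphoid list did not pass (adjusted p = 0.865), and whether other cells or a change of state explain these genes was not tested.

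Under carfilzomib itself, HSF1-/- and HSF1+/+ cells differed at 9545 genes, 4655 higher and 4890 lower in HSF1-/-. The heat shock list was lower (2 of 28 were higher, 24 lower, 2 did not pass, median -1.47). For the heat shock list, 2 were higher and 24 lower adjusted over the list alone, with adjusted p = 4.47e-08, and adjusted p = 0.419 with an estimated correlation. HSPH1 had 1914 ± 499 normalized reads in HSF1-/- and 18730.0 ± 6606 in HSF1+/+ (-3.27 ± 0.23, adjusted p = 1.21e-06), and DNAJB1 (-1.84 ± 0.33), HSPB1 (-2.20 ± 0.26) and HSPA8 (-1.29 ± 0.25) were lower as well. BAG3 did not differ by the test (0.02 ± 0.24, adjusted p = 0.946). Among proteasome genes, 8 were higher and 11 lower, and the list did not pass (adjusted p = 0.507). SESN2, a stress-induced inhibitor of mTORC1 signalling, was higher (3.51 ± 0.37), as was the growth-response factor gene EGR1 (5.42 ± 0.44).

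Carfilzomib against control in wild-type TF-1a measured the response to proteasome inhibition in this line from separate libraries. The proteasome genes rose (17 of 33 rose, 0 fell, 16 did not pass, median 0.97). The proteasome list had adjusted p = 3.68e-31, and adjusted p = 0.0799 with an estimated correlation, and 32 rose and 0 fell adjusted over the list alone. PSMC4 (ENSG00000013275, chromosome 19, 39971005 to 39981441), an ATPase subunit, rose from 4124 ± 335 to 10773 ± 1662 normalized reads (1.38 ± 0.26, limma adjusted p = 0.0237). GABARAPL1 rose from 597 ± 25.5 to 2961 ± 629 (2.29 ± 0.21), SQSTM1 by 1.98 ± 0.27, HMOX1 by 2.95 ± 0.36 and the cystine transporter gene SLC7A11 by 1.91 ± 0.30. NRF2 targets shifted upward (7 of 20 rose, 0 fell, 13 did not pass, median 1.09). For the NRF2 list, 11 rose and 0 fell adjusted over the list alone, with adjusted p = 2.37e-12, and adjusted p = 0.0799 with an estimated correlation. ER unfolded protein response genes shifted upward (2 of 25 rose, 0 fell, 23 did not pass, median 0.82). For the ER unfolded protein response list, 8 rose and 0 fell adjusted over the list alone, with adjusted p = 1.75e-10, and adjusted p = 0.104 with an estimated correlation. The heat shock list had no single gene past the test (0 of 30 rose, 0 fell, 30 did not pass, median 0.71). That heat shock list had adjusted p = 0.00573, and adjusted p = 0.776 with an estimated correlation, and 0 rose and 0 fell adjusted over the list alone. HSPA1A, whose reads are shared with its copy HSPA1B, stood at 3.10 ± 1.61 (adjusted p = 0.392) and rose in the fit of only the 2 groups (SE 0.52, adjusted p = 0.00898). The cyclin D1 gene CCND1 fell (-2.53 ± 0.38), and cell cycle genes shifted downward (0 of 31 rose, 5 fell, 26 did not pass, median -0.53). That cell cycle list had adjusted p = 6.12e-09, and adjusted p = 0.0795 with an estimated correlation, and 0 rose and 11 fell adjusted over the list alone. In the fit of only the 2 groups, 33 of 33 proteasome genes, 16 of 20 NRF2 targets, 22 of 25 ER unfolded protein response genes and 17 of 30 heat shock genes rose, and 18 of 31 cell cycle genes fell.

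By limma, 492 of 15296 genes passed in TF-1a under carfilzomib, 317 up and 175 down, and the groups did not overlap for any of the 492 (47.4% of all genes did not overlap, against 10% by chance). DESeq2 called 1729, the fit of only these 2 groups 4748, that fit with the replicate number as a block 5990, and the fit without the filter on low values 170. Without the library labelled TF-1a combination replicate 3 it was 4687. It was 52 and 53 without carfilzomib replicate 1 or 2, 62, 56 and 67 without control replicate 1, 2 or 3, and 217, 208 and 258 without Lys05 replicate 1, 2 or 3. Of the genes tested in the wild-type TF-1a and HSF1+/+ tables (13967), which share no control libraries, 440 were called in the same direction and 0 in opposite directions, against 64.6 upward and 30.9 downward for independent lists. The log2 fold changes correlated at 0.812 (Pearson) and 0.793 (Spearman) across genes.

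**Figure D3:**
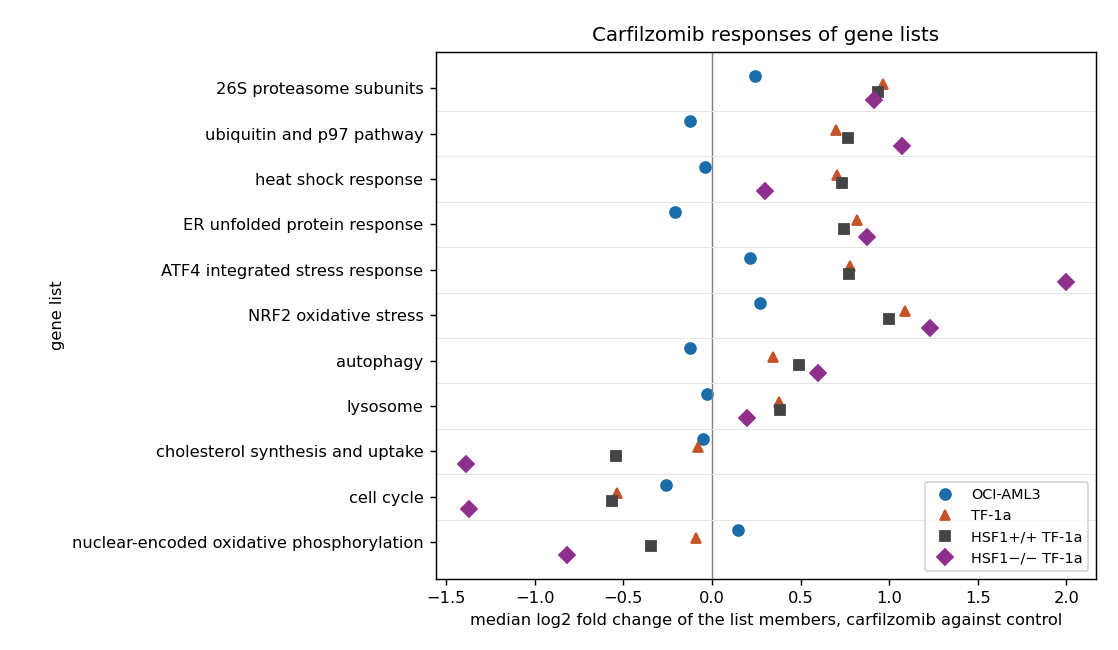
Median log2 fold change of the members of 11 gene lists, carfilzomib against control (x axis), in wild-type OCI-AML3 and TF-1a and in HSF1+/+ and HSF1-/- TF-1a; each symbol is one list in one comparison. The proteasome list lay at 0.24 in OCI-AML3 and at 0.97 in TF-1a.

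In OCI-AML3, carfilzomib against control asked the same question in a second AML line. The cystine transporter gene SLC7A11 had 709.8 ± 54.0 normalized reads under carfilzomib and 184 ± 29.4 in control, a rise of 1.95 ± 0.14 in the fit of only these 2 groups (adjusted p = 0.0301). The same fit called higher levels of SERPINB2 (2.56 ± 0.32), an inhibitor of plasminogen activators, and of PTGIS (2.24 ± 0.15), the prostacyclin synthase. The proteasome list moved upward by a small amount (0 of 33 rose, 0 fell, 33 did not pass, median 0.24). For the proteasome list, 0 rose and 0 fell adjusted over the list alone, with adjusted p = 6.43e-06, and adjusted p = 0.456 with an estimated correlation. Genes of MYC and ribosome biogenesis moved upward as well (0 of 25 rose, 0 fell, 25 did not pass, median 0.31). The MYC and ribosome biogenesis list had adjusted p = 7.98e-07, and adjusted p = 0.399 with an estimated correlation, and 0 rose and 0 fell adjusted over the list alone. SQSTM1 (-0.19 ± 0.09, adjusted p = 0.260) and GABARAPL1 (-0.62 ± 0.16, adjusted p = 0.0838) did not pass. In the planned 4-group fit, limma called 0 of 15137 genes, 447 had an unadjusted p below 0.05, and edgeR called 0 and DESeq2 83. The fit of only the 2 groups called 792 (403 up, 389 down), and with the replicate number as a block 3762. The fit without the block called 6 of 33 proteasome genes and 8 of 25 genes of MYC and ribosome biogenesis as rising.

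Responses of the lines to carfilzomib were compared in a joint fit of control and carfilzomib libraries. It was added after both tables were found to share one normalization. The response was more positive in TF-1a for proteasome genes (27 of 33 were positive, 0 negative, 6 did not pass, median 0.75). That proteasome list had adjusted p = 1.10e-14, and adjusted p = 0.269 with an estimated correlation, and 31 were positive and 0 negative adjusted over the list alone. So was that of the ubiquitin pathway (16 of 21 were positive, 0 negative, 5 did not pass, median 0.78). For the ubiquitin list, 16 were positive and 1 negative adjusted over the list alone, with adjusted p = 2.65e-08, and adjusted p = 0.269 with an estimated correlation. The ER unfolded protein response had more positive values in TF-1a (17 of 25 were positive, 0 negative, 8 did not pass, median 0.96). That ER unfolded protein response list had adjusted p = 7.32e-09, and adjusted p = 0.620 with an estimated correlation, and 19 were positive and 0 negative adjusted over the list alone. Heat shock genes also responded more in TF-1a (16 of 30 were positive, 0 negative, 14 did not pass, median 0.61). The heat shock list had adjusted p = 2.45e-06, and adjusted p = 0.705 with an estimated correlation, and 17 were positive and 1 negative adjusted over the list alone. The response was more negative in TF-1a for MYC and ribosome biogenesis (0 of 25 were positive, 14 negative, 11 did not pass, median -0.46). For the MYC and ribosome biogenesis list, 0 were positive and 14 negative adjusted over the list alone, with adjusted p = 6.26e-07, and adjusted p = 0.296 with an estimated correlation. SQSTM1 changed by 1.98 ± 0.21 in TF-1a and had -0.19 ± 0.21 in OCI-AML3, a difference of 2.17 ± 0.30 (adjusted p = 0.000442), and PSMC4 differed by 1.03 ± 0.15 (adjusted p = 0.000660). In all, 4078 of 14828 genes passed, 2103 with the larger value in TF-1a and 1975 with the smaller one. Within each line, this fit called 1669 (OCI-AML3) and 4916 (TF-1a) genes. Across 14064 genes tested in both tables, the log2 fold changes of the lines correlated at -0.018 (Pearson) and -0.073 (Spearman).

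Lys05 against control in TF-1a asked what inhibition of the lysosome did alone. Genes of cholesterol synthesis and uptake shifted upward (12 of 25 rose, 0 fell, 13 did not pass, median 1.27). The cholesterol list had adjusted p = 7.94e-19, and adjusted p = 0.00277 with an estimated correlation, where it still passed, and 20 rose and 0 fell adjusted over the list alone. INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235), which retains the SREBP activator in the ER, rose from 2543 ± 258 to 9994 ± 117 normalized reads (1.98 ± 0.21, limma adjusted p = 0.00223) and the sterol synthesis genes MSMO1 and SQLE by 1.74 ± 0.28 and 1.61 ± 0.30. Cell cycle genes fell (0 of 31 rose, 20 fell, 11 did not pass, median -1.04), among them the mitotic kinesins KIF4A (-1.94 ± 0.17) and KIF11 (-1.38 ± 0.17), and CDKN1A rose by 2.36 ± 0.38. The cell cycle list had adjusted p = 2.71e-26, and adjusted p = 0.00170 with an estimated correlation, where it still passed, and 0 rose and 26 fell adjusted over the list alone. NF-kB targets shifted upward (6 of 17 rose, 0 fell, 11 did not pass, median 1.46), including TNFAIP3 (2.40 ± 0.17), a feedback inhibitor of that pathway, and RELB (2.37 ± 0.36). That NF-kB list had adjusted p = 1.05e-10, and adjusted p = 0.0132 with an estimated correlation, where it still passed, and 9 rose and 0 fell adjusted over the list alone.

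SQSTM1 rose by 2.06 ± 0.27 in TF-1a under Lys05, and FNIP1 (1.46 ± 0.18) and FLCN (1.07 ± 0.23), partners in nutrient signalling at the lysosome, rose too. The lysosome list moved upward (5 of 47 rose, 1 fell, 41 did not pass, median 0.29). For the lysosome list, 6 rose and 1 fell adjusted over the list alone, with adjusted p = 0.00141, and adjusted p = 0.682 with an estimated correlation. ATF4 targets shifted upward (5 of 31 rose, 0 fell, 26 did not pass, median 0.75), with GDF15 at 2.75 ± 0.39. The ATF4 list had adjusted p = 1.32e-10, and adjusted p = 0.137 with an estimated correlation, and 10 rose and 0 fell adjusted over the list alone. In the fit of only the 2 groups, 24 of 25 cholesterol genes, 14 of 17 NF-kB targets, 24 of 31 ATF4 targets and 24 of 47 lysosomal genes rose (6 lysosomal genes fell), and 31 of 31 cell cycle genes fell. In all, 600 genes passed (324 up, 276 down). DESeq2 called 1840, the fit of only these 2 groups 6163, and the fit without the filter on low values 281. Without the library labelled TF-1a combination replicate 3 it was 4757. It was 179, 129 and 157 without Lys05 replicate 1, 2 or 3, 162, 134 and 156 without control replicate 1, 2 or 3, and 378 without carfilzomib replicate 2.

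In OCI-AML3, the fit of only the Lys05 and control groups called 143 genes. They included RENBP (2.11 ± 0.15, adjusted p = 0.00777), an enzyme of sugar metabolism, and SQSTM1 (0.58 ± 0.09, adjusted p = 0.0431). The lysosome list moved upward (0 of 47 rose, 0 fell, 47 did not pass, median 0.28), with the lysosomal enzymes ASAH1 at 0.99 ± 0.10 and TPP1 at 0.78 ± 0.08 and the cholesterol carrier NPC2 at 0.97 ± 0.14 in the 2-group fit. That lysosome list had adjusted p = 2.54e-06, and adjusted p = 0.795 with an estimated correlation, and 0 rose and 0 fell adjusted over the list alone. Cholesterol genes moved upward (0 of 24 rose, 0 fell, 24 did not pass, median 0.32). For the cholesterol list, 0 rose and 0 fell adjusted over the list alone, with adjusted p = 1.42e-06, and adjusted p = 0.613 with an estimated correlation. Cell cycle genes moved downward (0 of 31 rose, 0 fell, 31 did not pass, median -0.29). For the cell cycle list, 0 rose and 0 fell adjusted over the list alone, with adjusted p = 3.50e-07, and adjusted p = 0.553 with an estimated correlation. The 2-group fit called 5 of 47 lysosomal, 0 of 24 cholesterol and 0 of 31 cell cycle genes in these directions. Without Lys05 replicate 1, that fit gave 2.04 for RENBP, 0.59 for SQSTM1, 0.97 for ASAH1, 0.79 for TPP1 and 1.05 for NPC2 (adjusted p = 0.122 to 0.199), so none passed. The list medians were then 0.32, adjusted p = 6.86e-10 (lysosome), 0.45, adjusted p = 7.31e-07 (cholesterol) and -0.23, adjusted p = 1.17e-07 (cell cycle). With an estimated correlation none of these passed (adjusted p = 0.560, 0.700 and 0.700). In the planned fit over 4 groups, limma called 0 genes, 244 had an unadjusted p below 0.05, and edgeR called 0 and DESeq2 40. The 2-group fit called 143 (112 up, 31 down), 791 with the replicate number as a block, and 7 without Lys05 replicate 1. Without the library labelled OCI-AML3 combination replicate 1 or 3, the 4-group fit called 13 and 5.

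Between the lines, the response to Lys05 differed at 2842 of 14844 genes in the joint fit, 1397 with the larger value in TF-1a and 1445 with the smaller. The response of cell cycle genes was more negative in TF-1a (0 of 31 were positive, 25 negative, 6 did not pass, median -0.77). That cell cycle list had adjusted p = 5.35e-13, and adjusted p = 0.133 with an estimated correlation, and 0 were positive and 26 negative adjusted over the list alone. Cholesterol genes responded more positively there (18 of 25 were positive, 1 negative, 6 did not pass, median 0.86). That cholesterol list had adjusted p = 1.61e-10, and adjusted p = 0.288 with an estimated correlation, and 20 were positive and 1 negative adjusted over the list alone. ATF4 targets did too (18 of 32 were positive, 0 negative, 14 did not pass, median 0.79). For the ATF4 list, 21 were positive and 0 negative adjusted over the list alone, with adjusted p = 1.09e-08, and adjusted p = 0.157 with an estimated correlation. So did NF-kB targets (10 of 17 were positive, 0 negative, 7 did not pass, median 1.43). The NF-kB list had adjusted p = 3.58e-08, and adjusted p = 0.115 with an estimated correlation, and 10 were positive and 0 negative adjusted over the list alone. SQSTM1 rose by 2.06 ± 0.12 in TF-1a and by 0.58 ± 0.12 in OCI-AML3 (difference 1.48 ± 0.17, adjusted p = 0.000284), and INSIG1 differed by 1.74 ± 0.25 (adjusted p = 0.000964).

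Mitochondrial transcripts, chosen after their values were seen, split into opposite directions under Lys05 in both lines. The 12S ribosomal RNA gene MT-RNR1 (chromosome M, 648 to 1601) rose by 2.59 ± 0.14 in OCI-AML3 (adjusted p = 0.00328, 2-group fit) and by 2.44 ± 0.28 in TF-1a (adjusted p = 0.00138), and the 16S gene MT-RNR2 (1671 to 3229) by 1.34 ± 0.20 and 1.07 ± 0.19 (adjusted p = 0.0431 and 0.00605). In the 4-group fits neither ribosomal RNA passed (MT-RNR1 adjusted p = 1 and 0.0959, MT-RNR2 1 and 0.327), nor did any of the 13 mitochondrial messenger RNAs over all genes. The messenger RNAs had lower levels, with a median of -1.89 in OCI-AML3 (adjusted p = 2.91e-37, adjusted p = 0.129 with an estimated correlation) and -1.45 in TF-1a (adjusted p = 4.64e-07, adjusted p = 0.608 with an estimated correlation). Adjusted over the list alone in the 4-group fit, 13 fell in OCI-AML3 and 10 in TF-1a. MT-CO3, a subunit of cytochrome oxidase, fell in OCI-AML3 (-2.47 ± 0.27) and in TF-1a (-1.66 ± 0.19). The tRNA genes MT-TF, which lies directly before MT-RNR1, and MT-TV, between the ribosomal genes, were on the side of ribosomal RNA in the 2-group fits, with 3.33 ± 0.47 (adjusted p = 0.0353) and 1.66 ± 0.28 (adjusted p = 0.0524) in OCI-AML3 and 3.21 ± 0.21 (adjusted p = 0.000307) and 2.27 ± 0.27 (adjusted p = 0.00157) in TF-1a. MT-TL1, the tRNA gene directly after MT-RNR2, was on the side of the messenger RNAs (-1.59 ± 0.31, adjusted p = 0.0677, and -0.96 ± 0.27, adjusted p = 0.0319). Without OCI-AML3 Lys05 replicate 1, the 2-group fit gave 2.98 for MT-TF, 2.48 for MT-RNR1 and 1.498 for MT-TV (adjusted p = 0.199, 0.0487 and 0.220). It gave 1.17 for MT-RNR2, -2.62 for MT-CO3 and -1.97 for MT-TL1 (adjusted p = 0.280, 0.190 and 0.1205). The ratio of mitochondrial messenger RNA to ribosomal RNA was 2.93 to 3.46 in OCI-AML3 control and 0.267 to 0.323 with Lys05, and 2.81 to 4.02 and 0.560 to 0.578 in TF-1a. It was 0.203 to 0.274 in the combination labelled OCI-AML3 and 0.156 to 0.267 in that labelled TF-1a. There ribosomal RNA was above every control, as was messenger RNA except in OCI-AML3 replicate 1 and TF-1a replicate 3.

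**Figure D4:**
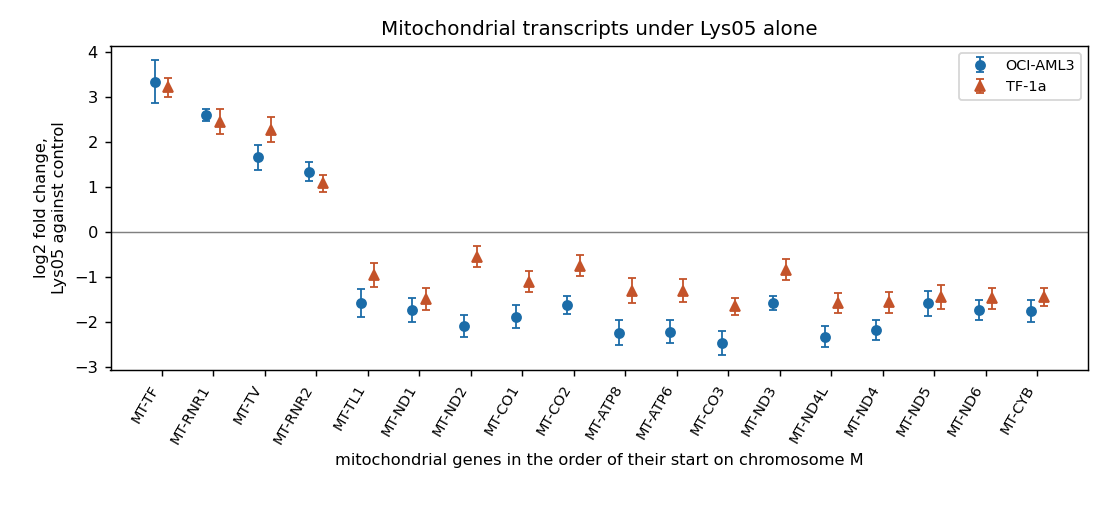
Log2 fold change of mitochondrial transcripts, Lys05 against control, in OCI-AML3 (circles) and TF-1a (triangles), in the order of their start on chromosome M; bars give the standard error of the 2-group fit (3 libraries per group). MT-RNR1 lay at 2.59 in OCI-AML3 and the messenger RNA MT-CO3 at -2.47.

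The combination of carfilzomib and Lys05 against control asked what blocking both degradation routes did. For each gene the first value comes from all libraries and the second from the fit without the library labelled replicate 3 of that combination group. In the groups labelled TF-1a, CDKN1A rose by 6.16 ± 0.38 (6.47 ± 0.36), DDIT3 by 4.66 ± 0.23 (4.49 ± 0.21) and GDF15 by 5.44 ± 0.39 (5.47 ± 0.42). Heat shock genes shifted upward (13 of 30 rose, 0 fell, 17 did not pass, median 1.69), with HSPA1A at 5.71 ± 1.61 (8.16 ± 0.51), DNAJB1 at 3.59 ± 1.26 (5.55 ± 0.27) and BAG3 at 3.56 ± 1.23 (5.50 ± 0.21). For the heat shock list, 13 rose and 0 fell adjusted over the list alone, with adjusted p = 1.81e-05, and adjusted p = 0.671 with an estimated correlation. Ribosomal protein genes rose (47 of 51 rose, 0 fell, 4 did not pass, median 1.25). For the ribosomal protein list, 47 rose and 0 fell adjusted over the list alone, with adjusted p = 1.87e-21, and adjusted p = 0.405 with an estimated correlation. Immediate early genes were higher too (13 of 15 rose, 0 fell, 2 did not pass, median 3.63). That immediate early list had adjusted p = 4.85e-06, and adjusted p = 0.463 with an estimated correlation, and 13 rose and 0 fell adjusted over the list alone. Cell cycle genes fell (0 of 31 rose, 22 fell, 9 did not pass, median -1.23), with the topoisomerase gene TOP2A at -2.64 ± 0.55 (-3.49 ± 0.11). The cell cycle list had adjusted p = 9.02e-09, and adjusted p = 0.0714 with an estimated correlation, and 0 rose and 25 fell adjusted over the list alone. These groups also differed in signs of RNA composition, with mitochondrial ribosomal RNA at 32.2%, 17.01% and 8.15% of reads in the libraries labelled TF-1a combination replicate 1, 2 and 3, against 1.05% to 1.12% in control. The nuclear RNA MALAT1, chosen after its values were seen, rose by 7.64 ± 0.27 (7.78 ± 0.28). It also rose under carfilzomib alone in HSF1+/+ (3.23 ± 0.38), HSF1-/- (3.66 ± 0.38) and wild-type TF-1a cells (2.10 ± 0.27), and had 0.02 ± 0.18 in OCI-AML3 (2-group fit, adjusted p = 0.976). The list medians without the library labelled replicate 3 were 2.81, adjusted p = 2.53e-13 (heat shock), 1.38, adjusted p = 1.01e-15 (ribosomal proteins), 4.63, adjusted p = 6.34e-09 (immediate early) and -1.17, adjusted p = 4.45e-05 (cell cycle), and none passed with an estimated correlation (adjusted p = 0.447, 0.574, 0.3498 and 0.3498).

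Of 15296 genes, 5705 passed in the groups labelled TF-1a combination against control (2602 up, 3103 down). The count was 10271 without the library labelled TF-1a combination replicate 3, and a fit of only the 2 groups called 2264, or 9540 without that library. Against carfilzomib alone, 5237 genes passed (2366 up, 2871 down), and 9943 without that library. The fit of only those 2 groups called 1460, or 8173 without it. In that comparison the proteasome genes shifted downward (1 of 33 rose, 16 fell, 16 did not pass, median -0.52), with PSMD2 at -1.95 ± 0.28 (-1.54 ± 0.12) and PSMC4 at -1.41 ± 0.26 (-1.07 ± 0.15), and the metal-binding metallothionein gene MT2A was higher (3.59 ± 0.27 and, without that library, 3.497 ± 0.281). The proteasome list had adjusted p = 0.000234, and adjusted p = 0.701 with an estimated correlation, and 1 rose and 18 fell adjusted over the list alone. The proteasome median was -0.36, adjusted p = 0.00632, without that library (adjusted p = 0.886 with an estimated correlation).

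The interaction of the drugs asked whether the combination differed from the sum of the single responses. In the groups labelled TF-1a it was negative for SQSTM1 (-2.16 ± 0.37 and, without the library labelled replicate 3, -2.28 ± 0.37), GABARAPL1 (-1.49 ± 0.30 and -1.67 ± 0.23) and the proteasome gene PSMD13 (-1.24 ± 0.17 and -1.28 ± 0.14). Proteasome genes had a negative interaction as a list (1 of 33 were positive, 7 negative, 25 did not pass, median -0.51). For the proteasome list, 1 were positive and 10 negative adjusted over the list alone, with adjusted p = 0.000560, and adjusted p = 0.727 with an estimated correlation. NRF2 targets had one as well (0 of 20 were positive, 6 negative, 14 did not pass, median -0.86). That NRF2 list had adjusted p = 0.00421, and adjusted p = 0.656 with an estimated correlation, and 0 were positive and 6 negative adjusted over the list alone. It was positive for MT2A (4.47 ± 0.38 and 4.38 ± 0.38) and DDIT3 (2.07 ± 0.33 and 1.89 ± 0.28). Ribosomal protein genes had a positive interaction as a list (21 of 51 were positive, 0 negative, 30 did not pass, median 0.77). That ribosomal protein list had adjusted p = 1.35e-15, and adjusted p = 0.656 with an estimated correlation, and 28 were positive and 0 negative adjusted over the list alone. HSPA1A had 1.93 ± 2.27 (adjusted p = 0.602) with all libraries and 4.38 ± 0.68 (adjusted p = 0.000454) without that library. The list medians without it were -0.35, adjusted p = 0.0139 (proteasome), -0.71, adjusted p = 0.0203 (NRF2) and 0.93, adjusted p = 3.15e-13 (ribosomal proteins), and the estimated correlation gave adjusted p = 0.842, 0.839 and 0.552. In all, 2329 genes passed (1033 positive, 1296 negative). DESeq2 called 3893. Without the library labelled combination replicate 3 limma called 7970. The count was 1521 and 1445 without carfilzomib replicate 1 or 2, 1425, 1350 and 1513 without Lys05 replicate 1, 2 or 3, and 1461, 1407 and 1376 without control replicate 1, 2 or 3.

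In the groups labelled OCI-AML3, the combination raised SQSTM1 by 3.14 ± 0.26 (3.42 ± 0.20 without the library labelled replicate 3), GABARAPL1 by 3.14 ± 0.46 (3.77 ± 0.25), HMOX1 by 7.30 ± 1.03 (7.71 ± 1.14) and ME1, a source of NADPH, by 3.27 ± 0.22 (3.27 ± 0.22). NRF2 targets rose (16 of 20 rose, 0 fell, 4 did not pass, median 1.55). The NRF2 list had adjusted p = 7.58e-12, and adjusted p = 0.0120 with an estimated correlation, where it still passed, and 16 rose and 0 fell adjusted over the list alone. Proteasome genes rose (25 of 33 rose, 0 fell, 8 did not pass, median 1.00), with ADRM1 at 1.74 ± 0.21 (1.83 ± 0.21) and PSMC4 at 1.69 ± 0.25 (1.96 ± 0.19). That proteasome list had adjusted p = 4.75e-16, and adjusted p = 0.0963 with an estimated correlation, and 28 rose and 0 fell adjusted over the list alone. Heat shock genes shifted upward (9 of 30 rose, 0 fell, 21 did not pass, median 0.91), with BAG3 at 3.18 ± 0.90 (1.85 ± 0.42) and HSPA1A at 4.31 ± 1.19 (2.76 ± 0.82, adjusted p = 0.0227). That heat shock list had adjusted p = 0.000105, and adjusted p = 0.627 with an estimated correlation, and 9 rose and 0 fell adjusted over the list alone. Cell cycle genes shifted downward (0 of 31 rose, 15 fell, 16 did not pass, median -1.30), with the replication helicase gene MCM2 at -1.80 ± 0.22 (-2.01 ± 0.17). For the cell cycle list, 0 rose and 18 fell adjusted over the list alone, with adjusted p = 3.22e-08, and adjusted p = 0.273 with an estimated correlation. With the library labelled replicate 3 left out, the heat shock list had 9 of 30 rising, 1 falling and a median of 0.39, adjusted p = 0.0445, against 0.91 with it. The other medians without it were 1.44, adjusted p = 2.71e-09 (NRF2), 1.15, adjusted p = 5.21e-17 (proteasome) and -1.37, adjusted p = 5.80e-09 (cell cycle). None of the 4 then passed with an estimated correlation (adjusted p = 0.838, 0.0944, 0.116 and 0.286). Mitochondrial ribosomal RNA made up 3.81%, 13.2% and 16.5% of reads in these 3 libraries, against 0.779% to 0.979% in control, and MALAT1 rose by 6.74 ± 0.82 (6.58 ± 0.92).

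By count, 3388 of 15137 genes passed in the groups labelled OCI-AML3 combination against control (1595 up, 1793 down). The count was 5532 by DESeq2, 6649 and 6287 without the library labelled combination replicate 1 or 3, and 1395, 1293 and 1727 without control replicate 1, 2 or 3, and a fit of only the 2 groups called 0, or 1527 without the library labelled replicate 3. Against carfilzomib alone, 3602 passed. There DESeq2 called 5698, limma 6508 and 6431 without the library labelled combination replicate 1 or 3 and 1917, 1822 and 2001 without carfilzomib replicate 1, 2 or 3, and a fit of only the 2 groups 0, or 2212 without the library labelled replicate 3. In that comparison HPDL, a gene of coenzyme Q synthesis, was lower (-5.42 ± 0.32 and, without that library, -5.48 ± 0.33). Genes of MYC and ribosome biogenesis fell (0 of 25 rose, 15 fell, 10 did not pass, median -0.97). That MYC and ribosome biogenesis list had adjusted p = 6.40e-07, and adjusted p = 0.345 with an estimated correlation, and 0 rose and 18 fell adjusted over the list alone. Their median without that library was -1.38, adjusted p = 3.68e-09 (adjusted p = 0.121 with an estimated correlation).

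The interaction in the groups labelled OCI-AML3 was positive for SQSTM1 (2.74 ± 0.37 and, without the library labelled replicate 3, 3.02 ± 0.27), GABARAPL1 (4.03 ± 0.64 and 4.66 ± 0.34) and the glutathione synthesis gene GCLM (2.71 ± 0.33 and 2.92 ± 0.25). NRF2 targets had a positive interaction as a list (8 of 20 were positive, 0 negative, 12 did not pass, median 1.23). For the NRF2 list, 13 were positive and 0 negative adjusted over the list alone, with adjusted p = 4.38e-08, and adjusted p = 0.0428 with an estimated correlation, where it still passed. So had proteasome genes (10 of 33 were positive, 0 negative, 23 did not pass, median 0.77). The proteasome list had adjusted p = 9.07e-12, and adjusted p = 0.139 with an estimated correlation, and 15 were positive and 0 negative adjusted over the list alone. It was negative for MYC (-2.88 ± 0.72 and -3.52 ± 0.49). Genes of MYC and ribosome biogenesis had negative values (0 of 25 were positive, 8 negative, 17 did not pass, median -1.22). The MYC and ribosome biogenesis list had adjusted p = 1.55e-08, and adjusted p = 0.208 with an estimated correlation, and 0 were positive and 16 negative adjusted over the list alone. The list medians without that library were 1.27, adjusted p = 5.75e-06 (NRF2), 0.93, adjusted p = 1.43e-12 (proteasome) and -1.46, adjusted p = 1.03e-10 (MYC and ribosome biogenesis), and none passed with an estimated correlation (adjusted p = 0.213, 0.213 and 0.0845). The signs for SQSTM1 and GABARAPL1 were opposite to those in TF-1a, but the difference between the lines in this interaction was not tested. In all, 991 genes passed (384 positive, 607 negative), 3085 by DESeq2 and 371 without the filter on low values. Leaving out a library moved the count to 3781, 1604 and 4147 (the libraries labelled combination replicate 1, 2 and 3), 291, 224 and 377 (carfilzomib 1, 2 and 3), 299, 271 and 262 (Lys05 1, 2 and 3) or 247, 259 and 325 (control 1, 2 and 3).

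**Figure D5:**
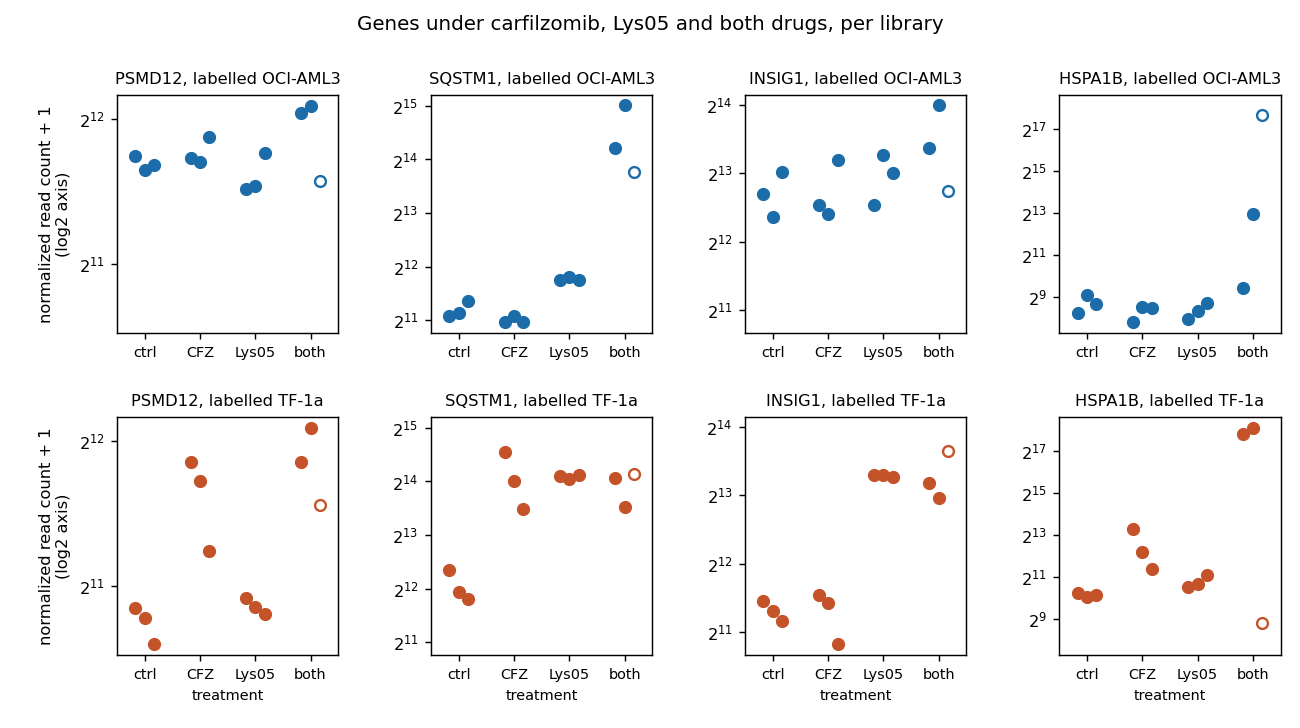
Normalized read counts plus 1 (log2 axis) of PSMD12, SQSTM1, INSIG1 and HSPA1B in each library under no drug (ctrl), carfilzomib (CFZ), Lys05 or carfilzomib plus Lys05 (both), by the line in the labels; open symbols are the libraries labelled carfilzomib plus Lys05 replicate 3. SQSTM1 rose by 1.98 on the log2 scale under carfilzomib in TF-1a.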

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

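Every test of an explanation in this part was chosen after the result it weighs was seen. Effects that differed between groups by a test of the difference were the interaction of HSF1 genotype and carfilzomib at 6345 genes, the interaction of carfilzomib and Lys05 at 2329 genes in the groups labelled TF-1a and 991 in those labelled OCI-AML3, and the difference between TF-1a and OCI-AML3 at 4078 genes for carfilzomib and 2842 for Lys05. Between the genotypes, the carfilzomib response of HSF1-/- minus HSF1+/+ cells differed by a mean of -0.67 for the heat shock list, 3.18 for immediate early genes and 1.402 for ATF4 targets, all on the log2 scale. With an estimated correlation between genes, none of these lists passed (adjusted p = 0.514, 0.322 and 0.514). Between the lines, the response to carfilzomib of TF-1a minus OCI-AML3 differed by a mean of 0.73 for proteasome genes. That list did not pass with an estimated correlation (adjusted p = 0.269), and doses were not given for either line.

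Regrouping libraries at random asked only whether chance can be excluded. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. There only the real split reached the real count for TF-1a and HSF1 comparisons and the combination labelled OCI-AML3, with a highest other value of 0. For carfilzomib and Lys05 in OCI-AML3 the real count was 0, which all 10 reached. Of 100 splits each, 1 reached the real count for the drug interaction labelled OCI-AML3 (991, highest other 29) and TF-1a (2329, 1190). The same held for genotype and carfilzomib (6345, 2835) and the line difference under carfilzomib (4078, 3175). Under Lys05, 4 of 100 splits reached 2842 (highest other 4668). Regrouping breaks the single effects too, so these shares cannot exclude chance for an interaction or line difference alone. These splits also ignore the replicate numbers, which paired carfilzomib and control in both lines, so the carfilzomib difference was retested with a replicate block. Of splits that part every pair, 1 of 32 (the real one) reached 4952. The highest other, 4081, kept the real grouping in TF-1a. For Lys05 only the OCI-AML3 samples passed the pairing check. The TF-1a correlations were 0.258, 0.0847 and 0.332, against a threshold of 0.1, so pairing there is not excluded. The block was used in OCI-AML3 only, with splits parting every OCI-AML3 pair and any split of TF-1a. Of these, 3 of 80 reached the real count of 3595, and the highest other, 5478, kept the TF-1a grouping too. The splits within pairs share that limit, so chance stays open there.

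The libraries labelled carfilzomib plus Lys05 replicate 3 stood with the other cell line. An exchange of the labels predicts that each holds the other line's transcripts at full level, and the lower of the 2 medians was 104.2%. RNA of the other line mixed into a rightly labelled library predicts that the labelled line's transcripts stay, and the higher median was 0.141%. These values argue against mixing for both libraries. A response of the cells predicts the same in replicates 1 and 2, where the highest median was 0%. The values suggest an exchange, which only the source material can settle, and the labels were kept.

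The library labelled OCI-AML3 Lys05 replicate 1 held low levels of TF-1a transcripts. Carry-over of RNA or reads from TF-1a predicts one common share over genes, and 89.1% of the TF-1a-specific genes lay within 2 times the median share. A response to Lys05 predicts the same in replicates 2 and 3, where the higher median was 0%. The values are consistent with carry-over and not with a response.

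Mitochondrial ribosomal RNA was higher and mitochondrial messenger RNA lower under Lys05 alone in both lines. A scaling or depth difference would move them together, but the ratio of messenger to ribosomal RNA was lower in every Lys05 library than in every control library of its line, so it cannot account for the pattern. The smaller fall between group means was 5.70 times, in TF-1a. Fewer mitochondria would lower ribosomal RNA, but in both lines MT-RNR1 and MT-RNR2 reads were higher in every Lys05 library than in every control. The smaller MT-RNR2 log2 fold change was 1.07 ± 0.19 (TF-1a, 2-group fit). Capture of each RNA was not tested, so reads cannot exclude less mitochondrial RNA. A loss that grows with distance along the heavy strand predicts a negative Spearman rho over its 12 messenger RNAs. It was 0.014 in OCI-AML3 (permutation p = 0.974) and -0.448 in TF-1a (permutation p = 0.147), which cannot tell. Termination of transcription after the ribosomal genes, at the site within MT-TL1, was not tested and stays open. MT-ND6, the messenger RNA of the other strand, had lower levels too (-1.74 ± 0.22 and -1.48 ± 0.24 on the log2 scale in OCI-AML3 and TF-1a, 2-group fits), which termination on the heavy strand alone would not predict. It did not pass in the 4-group fits (adjusted p = 1 and 0.0914), nor in the OCI-AML3 2-group fit without Lys05 replicate 1 (adjusted p = 0.190). The protocol does not keep the strand, so reads antisense to that gene cannot be told apart from its own.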

How the results depend on the processing

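A pseudocount of 8, rescaled libraries, edgeR and the replicate number as a block in the 4-group fit each left the 19 counts and tests they applied to within 1.5 times. The other alternatives moved counts as follows, and the cause was not tested unless fewer libraries are its own construction. DESeq2 called, in OCI-AML3, 83 (carfilzomib), 40 (Lys05), 5532 (combination), 5698 (combination against carfilzomib) and 3085 (interaction). In TF-1a it called 1729 (carfilzomib), 1840 (Lys05) and 3893 (interaction). Without the filter on low values, limma called 371 (OCI-AML3 interaction), 170 (TF-1a carfilzomib) and 281 (TF-1a Lys05). In fits of only the groups compared it called, in OCI-AML3, 792 (carfilzomib), 143 (Lys05), 0 (combination) and 0 (combination against carfilzomib), in TF-1a 4748, 6163, 2264 and 1460 in the same order, and 4874 for untreated HSF1-/- against HSF1+/+. Chosen, like the block, after the data were seen, 2-group fits without the doubted libraries called 7 (Lys05, OCI-AML3), 1527 and 2212 (combination against control and carfilzomib, labelled OCI-AML3) and 9540 and 8173 (labelled TF-1a).

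With the replicate block, the 2-group fits called 3762 (OCI-AML3 carfilzomib), 791 (OCI-AML3 Lys05) and 5990 (TF-1a carfilzomib), where the numbers paired the samples. Where they share only a number, the block gave 0 and 0 (combination labelled OCI-AML3 against control and carfilzomib), 7167 (TF-1a Lys05), 3 and 0 (the same labelled TF-1a), 9070 (HSF1+/+ carfilzomib) and 5386 (untreated HSF1-/- against HSF1+/+). Every sample correlated best with its own number in TF-1a Lys05 and in HSF1+/+ and HSF1-/- carfilzomib (3 of 3). This held for 2 of 3 pairs in the OCI-AML3 combination comparisons and in both comparisons of genotypes, for 1 for TF-1a carfilzomib and the combination, and for 0 for the TF-1a combination and control. The block changed no other call of a count.

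Of the 185 list tests past the threshold, 7 held with an estimated correlation. Of the calls shared by TF-1a and HSF1+/+ carfilzomib (440), 198 had a log2 fold change of at least 1 in both, and the 2-group fits shared 3822. For OCI-AML3 and TF-1a, 0 became 105, with 216 in opposite directions, against 64.3 upward and 56.0 downward for independent lists. Leaving out 1 library gave, for OCI-AML3, 0 to 13 (Lys05), 1293 to 6649 (combination), 1822 to 6508 (against carfilzomib) and 224 to 4147 (interaction), and for TF-1a 52 to 4687 (carfilzomib), 129 to 4757 (Lys05), 3942 to 10271, 3654 to 9943 and 1350 to 7970. The ranges were 3721 to 7445 for HSF1+/+ carfilzomib and 898 to 3222 for untreated genotypes. Only the erythroid list of the combination labelled TF-1a against control changed direction in the list test, which compares it with all other genes. Its mean stayed negative, from -4.08 without the library labelled replicate 1 to -0.011 without the one labelled replicate 3, where it was no longer called (adjusted p = 0.996). Of 150 results for named genes, none reversed in any alternative.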

Other observations

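The tests in this part were those of the report, but which of their results to describe here was chosen after they were seen. In HSF1+/+ cells, nuclear genes of oxidative phosphorylation also shifted downward under carfilzomib (0 of 42 rose, 19 fell, 23 did not pass, median -0.34). For the oxidative phosphorylation list, 0 rose and 21 fell adjusted over the list alone, with adjusted p = 1.12e-07, and adjusted p = 0.447 with an estimated correlation. Cell cycle genes fell as well (0 of 31 rose, 16 fell, 15 did not pass, median -0.57), with PCNA at -1.01 ± 0.17. That cell cycle list had adjusted p = 2.53e-06, and adjusted p = 0.446 with an estimated correlation, and 0 rose and 17 fell adjusted over the list alone. The antiapoptotic gene MCL1 rose by 2.60 ± 0.17 under carfilzomib in HSF1-/- cells, with an interaction of 1.89 ± 0.23 (limma adjusted p = 0.000183).

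In wild-type TF-1a, ATF4 targets shifted upward under carfilzomib (5 of 31 rose, 0 fell, 26 did not pass, median 0.78), with ATF4 itself at 1.15 ± 0.17. That ATF4 list had adjusted p = 1.75e-10, and adjusted p = 0.104 with an estimated correlation, and 11 rose and 0 fell adjusted over the list alone. The monocyte marker CD14 rose by 7.43 ± 0.43 in the groups labelled TF-1a carfilzomib plus Lys05 against control (7.48 ± 0.42 without the library labelled replicate 3), with a positive interaction of the drugs (5.29 ± 0.60, without that library 5.34 ± 0.56). In the groups labelled OCI-AML3, lysosomal genes shifted upward with the combination (12 of 47 rose, 0 fell, 35 did not pass, median 0.59), among them the cathepsin gene CTSL (2.47 ± 0.39, without that library 2.50 ± 0.44) and the sialidase gene NEU1 (2.15 ± 0.26, without that library 2.33 ± 0.24). The lysosome list had adjusted p = 0.000159, and adjusted p = 0.618 with an estimated correlation, and 12 rose and 0 fell adjusted over the list alone. The lysosome median without that library was 0.81, adjusted p = 2.49e-13 (adjusted p = 0.0944 with an estimated correlation).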
